A study of Mus musculus with 24 samples.

How the data were processed

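RNA was measured in mouse embryonic fibroblasts (MEFs), wild type or Mof knockout, and in MPC5 podocytes with a scrambled control or a Mof knockdown, each given vehicle (DMSO) or Adriamycin for 24 h. This made 8 groups of 3 samples, 24 in all. The submitters' notes give RNeasy extraction, poly(A) libraries and Illumina sequencing. They do not say whether the 3 samples of a group are separate cultures, so the p-values measure the spread between these samples, which may be technical. Per the submitters' processing notes, the authors used TopHat2 2.0.13, featureCounts 1.4.5-p1 and DESeq2 1.4.1 with GRCm38.

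The deposited files are 4 tables of comparisons made by the authors, 1 for each cell type and drug condition. The signal in them is the mean count over the samples of the table after division by size factors, made by the authors. The log2 fold change and its standard error were made by the authors with DESeq2. The score is the Wald statistic of the authors, checked to be the fold change over its standard error to within 1.4e-13. The p-value and its Benjamini-Hochberg adjusted p-value are those of the authors. The version of DESeq2 the authors name shrinks log2 fold changes by default, most for genes with few reads; whether the authors kept that default is not stated in the notes, and the values were used as deposited. The direction was read as Mof-depleted over control from the sign of Kat8, which was negative in each table. Each table was normalized on its own by the authors, so mean counts of different tables were not tested against each other. Both MEF tables list 43626 genes. The podocyte tables were checked to list only genes with an adjusted p below 0.05, and the number of genes tested, 13876 with vehicle and 17184 with Adriamycin, was recovered from the ratio of p to adjusted p. No file holds a value per sample. Depth per library is therefore unknown, and the precision of a gene is its standard error in the table, whose median over changed genes was 0.124 and 0.131 in MEFs with vehicle and Adriamycin and 0.130 and 0.0847 in podocytes. No SD, number of samples by direction, left-out sample, other split of the samples or estimated correlation between genes could be computed. Adriamycin was not compared with vehicle, since no table does so.

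A gene counted as changed when the adjusted p of the authors lay below 0.05. Coordinates and gene types come from GENCODE M21 (GRCm38). Named genes were set by a rule: Kat8; the 10 highest and 10 lowest log2 fold changes among changed genes with a mean count of at least 100 and a symbol that is not that of a predicted gene; of each list up to 4 members, the 2 higher and 2 lower with the smallest adjusted p, or the 2 with the smallest p where none passed; for the difference between drug conditions the 5 largest in each direction; and for the overlap of cell types the 10 changed in both whose smaller absolute fold change was largest. Not every gene that this rule gives is reported here.

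The 31 gene lists held 1216 members (1200 distinct genes), of which 2 were not matched. They cover MOF and its paralogs, the MSL and NSL complexes, p53 targets, the apoptosis machinery, homologous recombination and Fanconi anaemia repair, non-homologous end joining, lysosome, autophagy, endosomal trafficking, the nuclear-encoded respiratory chain, mitochondrially encoded genes, the mitochondrial ribosome, cytosolic ribosomal proteins, mitosis and DNA replication. The others cover podocyte, fibroblast and mesenchymal, macrophage and leukocyte, endothelial, epithelial, skeletal muscle, neural, interferon-stimulated, inflammatory and secretory genes, the integrated stress and unfolded protein response, the antioxidant response, cholesterol synthesis, glycolysis and hypoxia, the primary cilium, actin cytoskeleton and focal adhesion, and housekeeping reference genes. Each list with at least 5 measured members was tested with cameraPR (limma 3.58.1, R 4.3.3) on the deposited statistic with a preset correlation of 0.01, Benjamini-Hochberg over the lists. In podocytes the test set a list against the other genes past the threshold only. In MEFs the members were also adjusted over the list alone. On simulated statistics, drawn independently for each gene, a shift of 1 SD was recovered in 100% of 50 draws. Of the unshifted lists, 0.0690% were called. Genes that move together were not simulated, so this share does not measure false calls in the data.

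The difference between drug conditions was the log2 fold change with Adriamycin less that with vehicle, over the root of the summed squared standard errors, with a normal p and Benjamini-Hochberg adjustment. On simulated fold changes (20 draws, 200 of 13973 genes changed, errors independent between genes) it recovered 20.1% of changes of 0.5, with 3.36% of its calls false. It recovered 67.2% of changes of 1, with 5.15% of its calls false. Apart from the set changes, both simulated conditions had the same true fold changes, so unequal shrinkage between tables was not simulated. These shares therefore do not measure false calls in the data. The number of draws was raised from 1 to 20 after the first output was seen. Overlaps of changed genes and of directions were tested with Fisher's exact test. The median of X-linked less autosomal genes was tested with 100000 permutations, after the statistic, first computed against all genes, was corrected to the planned one. Intervals of 95% come from 10000 bootstrap draws of genes. Genes within 1 Mb of Kat8 were counted.

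Alternatives were adjusted p thresholds of 0.01 and 0.1, a change of at least 2-fold, minimum mean counts, recentring on the median with an absolute log2 fold change above 0.58, a preset correlation of 0.05, ranks, the fold change as the statistic, division by the slope between tables, other windows (0.25 and 5 Mb), and regression on GC content and transcript length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.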

Results

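The series measured gene expression in mouse cells labelled as Mof knockout or Mof knockdown and in their controls, with and without Adriamycin. MOF, the product of Kat8, is a histone H4 acetyltransferase that acts in the MSL and NSL complexes. Adriamycin (doxorubicin) is an anthracycline that poisons topoisomerase II and damages DNA. Mouse embryonic fibroblasts (MEFs, passage 2) were wild type or Mof knockout. MPC5 cells, a line of mouse glomerular podocytes, were differentiated (passage 20) and carried a scrambled control or a Mof knockdown. The drug was given for 24 h at 0.1 µg/ml to MEFs and 0.25 µg/ml to podocytes, and the other samples received vehicle (DMSO). The 24 samples formed 8 groups of 3. The values come from 4 comparison tables made by the authors, each setting Mof-depleted against control samples of the same cell type and drug condition. These tables hold no value per sample, so the depth of each library is unknown. The mean normalized counts summed to 2.11e+07 in each of the MEF tables. Fold changes below are Mof-depleted over control on the log2 scale, and each is given with the standard error (SE) of the authors' deposited table.

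Kat8 fell in all 4 comparisons. In MEFs, the log2 fold change of Kat8 (ENSMUSG00000030801, GRCm38 chromosome 7, 127912516 to 127925837, protein coding) in the authors' deposited table was -1.96 ± 0.20 (SE) with vehicle and -1.71 ± 0.16 with Adriamycin, which leaves 25.7% and 30.5% of the control level. In podocytes the Kat8 change was -1.49 ± 0.15 with vehicle and -1.24 ± 0.14 with Adriamycin in the authors' deposited table, or 35.6% and 42.3% left. The adjusted p, from DESeq2 as run by the authors, lay between 2.84e-25 and 2.99e-19. The mean normalized count of Kat8 over the samples of a table was 160 to 262. The direction of the fold changes was itself read from the sign of Kat8, so these values do not test the sample labels. Prss8 overlaps Kat8 on the opposite strand, and whether the counting used strand is not given in the sources used here. The number of genes past an adjusted p of 0.05 ran from 1990 in podocytes with vehicle to 9578 with Adriamycin. In MEFs it was 5851 with vehicle and 4622 with Adriamycin.

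**Figure D1:**
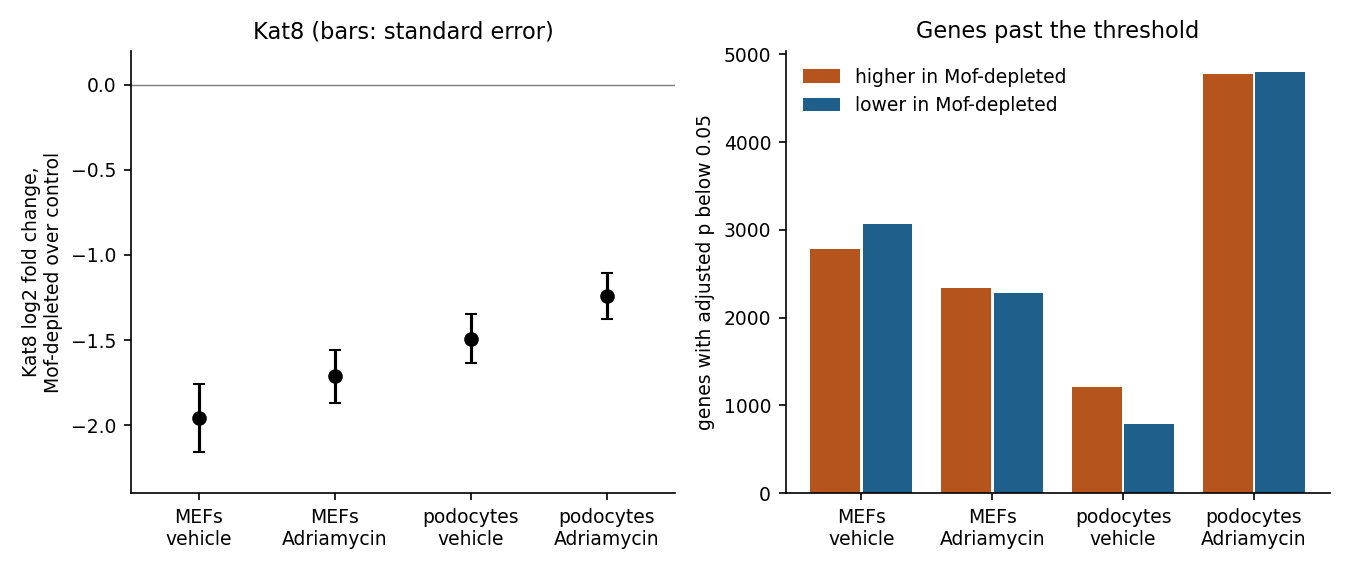
Left, log2 fold change of Kat8 (Mof-depleted over control) in the 4 comparisons, with bars of 1 SE, all between -1.96 and -1.24. Right, number of genes with an adjusted p below 0.05 in each authors' deposited table, higher (orange) or lower (blue) in Mof-depleted cells, from 1990 genes in podocytes with vehicle to 9578 with Adriamycin.

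To ask what loss of MOF changed in fibroblasts not given Adriamycin, knockout and wild-type MEFs were compared under vehicle. Interferon-stimulated genes rose together: all 44 tested members were higher, with a median log2 fold change of 2.41. Mitotic genes fell together: all 60 tested members were lower, with a median of -1.30. Genes of DNA replication fell (45 of 50), as did genes of homologous recombination and Fanconi anaemia repair (36 of 46). Targets of p53 rose (34 of 41, with 2 lower), and so did lysosomal genes (49 of 68, with 2 lower). In all, 5851 of 15605 tested genes changed in the authors' deposited table, 2785 higher and 3066 lower, of which 860 rose and 462 fell at least 2-fold.

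Among named genes with a mean count of at least 100, the largest increase under vehicle was that of Esr1, the oestrogen receptor alpha (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614). It was at 7.11 ± 0.21 (SE, 138-fold) with a mean normalized count of 1241 in the authors' deposited table. Its adjusted p, from DESeq2 as run by the authors, was 5.93e-251. Of the 13 tested genes within 1 Mb of Esr1, 3 rose, and their median log2 fold change was -0.12. Whether the Esr1 reads come from the gene itself or from a transgene carrying Esr1 sequence could not be told. Among interferon-stimulated genes in the authors' deposited table, Ifi44 rose by 5.50 ± 0.40, Isg15, a ubiquitin-like modifier, by 4.76 ± 0.44, Usp18, the protease that removes it, by 5.16 ± 0.49, and Irf7, a transcription factor of the interferon response, by 4.61 ± 0.35. Ifit1 (4.42 ± 0.32), Rtp4 (4.07 ± 0.38), Ifit3 (3.85 ± 0.27), Xaf1 (3.85 ± 0.33) and the antigen transporter Tap1 (2.10 ± 0.15) rose as well in the authors' deposited table. Svop, a gene outside the lists, rose by 4.07 ± 0.32. The matrix metalloproteinases Mmp13 (3.09 ± 0.21) and Mmp3 (2.98 ± 0.20) rose among inflammatory and secretory genes in the authors' deposited table, where 11 of 36 members rose and 3 fell. Genes that fell in the authors' deposited table, among those with a mean count of at least 100, included Kat8, Spc24, a kinetochore protein (-2.08 ± 0.18), the serine protease gene Klk8 (-2.08 ± 0.22), Abi3bp (-2.08 ± 0.26), DNA polymerase theta (Polq, -1.96 ± 0.17), the connexin gene Gjb2 (-1.94 ± 0.35), the phosphatase Cdc25c (-1.86 ± 0.16). Others that fell were the centromere gene Mlf1ip (-1.84 ± 0.22), aggrecan (Acan, -1.84 ± 0.35) and the nuclease gene Eme1 (-1.84 ± 0.19).

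Members of the gene lists moved as follows under vehicle. In the authors' deposited table, the mitotic cyclin Ccnb2 was at -1.80 ± 0.11 and the spindle checkpoint kinase Bub1 at -1.76 ± 0.11. Of the replication genes, Uhrf1 (-1.13 ± 0.08) and thymidine kinase Tk1 (-1.22 ± 0.10) had the smallest adjusted p in the authors' deposited table, and of the repair genes Fanci (-1.80 ± 0.16) and Rad54l (-1.78 ± 0.16). Trp53inp1 (1.96 ± 0.15) and Dcxr (1.78 ± 0.14) rose among p53 targets in the authors' deposited table, while Ckap2 (-0.36 ± 0.09) and Dram1 (-0.72 ± 0.27) fell. Lysosomal Npc2, a cholesterol-binding protein (1.12 ± 0.07), and the protease Ctsd (1.41 ± 0.10) rose in the authors' deposited table, as did the autophagy receptor Sqstm1 (1.23 ± 0.10). Adjusted over the list alone, the counts were 44 higher for interferon-stimulated genes, 60 lower for mitosis, 45 lower for replication, 38 lower for homologous recombination, 34 higher and 2 lower for p53 targets, and 49 higher and 2 lower for the lysosome.

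A competitive test of each list against the other tested genes (cameraPR of limma, Benjamini-Hochberg over 31 lists) called 18 lists under vehicle. Its adjusted p was 5.01e-100 for mitosis, 1.48e-44 for interferon-stimulated genes, 1.25e-31 for DNA replication, 1.50e-24 for the lysosome, 1.74e-21 for p53 targets and 2.02e-17 for homologous recombination and Fanconi anaemia repair. Genes of the mitochondrial ribosome fell (46 of 77, with 2 higher; median -0.32; adjusted p 5.61e-07). Those of the antioxidant response rose (18 of 32; median 0.33; adjusted p 6.24e-07). Genes of the primary cilium fell (28 of 60, with 2 higher; median -0.45; adjusted p 8.18e-05). Also called were endosomal trafficking (30 higher and 10 lower of 69, adjusted p 0.000272), the nuclear-encoded respiratory chain (4 higher and 30 lower of 76, 0.00470), autophagy (17 higher and 7 lower of 44, 0.00652), inflammatory and secretory genes (0.00456), mitochondrially encoded genes (4 higher of 15, 0.0141), non-homologous end joining (4 lower of 10, 0.0479), podocyte genes (12 higher and 3 lower of 46, 0.0217), skeletal muscle genes (7 higher of 15, 0.00987), and macrophage and leukocyte genes (9 higher of 19, 0.0197). The 4 mitochondrial genes that rose included both ribosomal RNAs, mt-Rnr1 (1.02 ± 0.08) and mt-Rnr2 (0.67 ± 0.07), in the authors' deposited table. The leukocyte genes that rose included the macrophage receptor gene Emr1 (1.21 ± 0.25), the complement gene C1qa (1.01 ± 0.27), and Lyz2 (1.29 ± 0.36), a lysozyme gene with a mean normalized count of 1924, in the authors' deposited table. Lyz2 was chosen after its values were seen. The leukocyte genes moved in the same comparison as the interferon-stimulated genes.

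With a preset correlation of 0.05 between genes in place of 0.01, 10 of the 18 calls were left. Over all alternatives, the adjusted p ran from 0.0431 to 0.121 for non-homologous end joining, 0.00455 to 0.615 for autophagy, 0.000885 to 0.106 for the respiratory chain, 0.00278 to 0.909 for mitochondrially encoded genes, 0.00730 to 0.151 for podocyte genes, 0.00104 to 0.0897 for leukocyte genes, 1.52e-06 to 0.0559 for skeletal muscle genes, 0.00156 to 0.0659 for inflammatory genes and 0.000156 to 0.574 for endosomal trafficking. No correlation could be estimated, since that needs values per sample.

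The remaining lists did not pass the test under vehicle, with adjusted p between 0.0784 and 0.617. With the fold change as the statistic, epithelial genes (adjusted p 0.00413, range over alternatives up to 0.563) and neural genes (0.0194, up to 0.280) passed it. Of MOF and its paralogs, Kat8 and Kat6a (-0.28 ± 0.08 in the authors' deposited table) fell. The MSL and NSL complexes had 4 members higher and 4 lower of 11, the apoptosis machinery 6 and 4 of 30, cytosolic ribosomal proteins 9 and 2 of 79 (1 and 1 adjusted over the list alone), and fibroblast and mesenchymal genes 6 and 11 of 40. Endothelial genes had 2 members higher of 12, epithelial genes 5 higher and 2 lower of 15, neural genes 5 and 1 of 13, and the integrated stress and unfolded protein response 10 and 17 of 40. Cholesterol synthesis had 1 member higher and 6 lower of 25, glycolysis and hypoxia 7 and 1 of 30, actin cytoskeleton and focal adhesion 9 and 8 of 52, and housekeeping reference genes 5 and 5 of 15. For the fibroblast list the median (-0.15) and the mean (0.01) differed in sign, and so they did for the stress response (-0.11 and 0.03). B2m, the light chain of class I antigen presentation and a reference gene, rose by 1.28 ± 0.12 in the authors' deposited table.

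The same comparison was made in MEFs given Adriamycin. Lysosomal genes rose (40 of 68, with 5 lower; median 0.39), cytosolic ribosomal protein genes rose by small amounts (67 of 79; median 0.27), and interferon-stimulated genes rose (28 of 42; median 0.87). Genes of the antioxidant response (19 of 31; median 0.45) and p53 targets (26 of 41; median 0.28) rose, and genes of the primary cilium fell (33 of 59, with 1 higher; median -0.44). Of 14139 tested genes, 4622 changed in the authors' deposited table, 2342 higher and 2280 lower, of which 342 rose and 212 fell at least 2-fold.

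Among named genes with a mean count of at least 100, Esr1 was again highest with Adriamycin. It was at 5.73 ± 0.15 with a mean normalized count of 1514 and an adjusted p listed as 0 in the authors' deposited table. The source of the Esr1 reads stays open here too. Mmp3 (2.66 ± 0.28), Usp18 (2.24 ± 0.26), Bst2, a virus-restricting membrane protein (2.23 ± 0.23), and Mmp13 (2.21 ± 0.21) rose among genes with a mean count of at least 100 in the authors' deposited table. So did the tight junction gene Cldn4 (2.19 ± 0.37), the butyrophilin gene Btn1a1 (2.06 ± 0.21), Ifi44 (2.00 ± 0.31), the triglyceride synthesis enzyme Dgat2 (1.92 ± 0.26) and Cnbd2 (1.86 ± 0.17) in the authors' deposited table. Genes that fell, with the same minimum count, included Abi3bp (-2.56 ± 0.29), the phosphatase Ptprb (-1.76 ± 0.31), Kat8, Klhl23 (-1.49 ± 0.23) and Gjb2 (-1.49 ± 0.27) in the authors' deposited table. Others were the magnesium transporter Nipa1 (-1.48 ± 0.23), monoamine oxidase B (Maob, -1.47 ± 0.35), the growth factor Fgf10 (-1.47 ± 0.20), Fndc4 (-1.47 ± 0.23) and Tstd3 (-1.45 ± 0.20). The cathepsin Ctsl (1.03 ± 0.08), Npc2 (0.88 ± 0.08), the ferritin light chain gene Ftl1 (0.66 ± 0.09) and the peroxiredoxin gene Prdx1 (0.53 ± 0.08) rose with Adriamycin in the authors' deposited table. Among cilium genes, Tctn2 (-1.35 ± 0.15) and Ttc21b (-0.79 ± 0.12) fell and the kinesin gene Kif17 rose (1.15 ± 0.26) in the authors' deposited table. Of the p53 targets, Gdf15 (1.42 ± 0.17) and Cgref1 (0.83 ± 0.12) rose in the authors' deposited table, and the stress-response transcription factors Ddit3 (2.83-fold) and Atf3 (1.30 ± 0.17) rose too.

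With Adriamycin the list test called 13 lists in MEFs. The adjusted p was 1.05e-16 for both the lysosome and cytosolic ribosomal proteins, 6.20e-13 for interferon-stimulated genes, 1.44e-08 for the primary cilium, 3.31e-08 for the antioxidant response and 1.70e-06 for p53 targets, and these 6 held with a correlation of 0.05. Adjusted over the list alone, 43 lysosomal genes were higher and 5 lower, 72 ribosomal protein genes were higher, 30 interferon-stimulated genes were higher and 1 lower, and 34 cilium genes were lower and 1 higher. Mitosis (2 higher and 10 lower of 57; adjusted p 0.0197), DNA replication (4 and 12 of 47; 0.0274), homologous recombination (2 and 10 of 43; 0.0274), endosomal trafficking (23 and 6 of 69; 0.00355), the respiratory chain (4 and 21 of 75; 0.0197), the integrated stress and unfolded protein response (14 and 4 of 40; 0.0113) and glycolysis and hypoxia (12 and 2 of 29; 0.0197) were called too. These 7 calls ended with a correlation of 0.05 (adjusted p 0.141 to 0.195), and over all alternatives their adjusted p ran up to 0.294 for homologous recombination, 0.261 for the respiratory chain, 0.248 for mitosis, 0.191 for DNA replication, 0.183 for endosomal trafficking and glycolysis, and 0.141 for the stress response. The mitotic genes that rose were the cyclin gene Ccnf (0.97 ± 0.16) and the kinetochore gene Spc25 (0.65 ± 0.18) in the authors' deposited table. No leukocyte gene passed the threshold with Adriamycin, and Lyz2 was at 0.73 ± 0.39 with an adjusted p of 0.145 in the authors' deposited table.

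To test whether the drug changed the effect of Mof loss, the fold changes of the MEF tables were compared gene by gene. Among the named genes with lower values under Adriamycin were interferon-stimulated genes: the change with Adriamycin less that with vehicle was -3.51 ± 0.51 for Ifi44, -3.22 ± 0.45 for Irf7, -3.01 ± 0.60 for Isg15 and -2.92 ± 0.55 for Usp18, all from the authors' deposited table of each drug condition. Svop differed by -3.33 ± 0.36. The 5 named genes that moved the other way were Cep128, a centriole component (2.29 ± 0.31), Fam83d, a spindle protein (1.78 ± 0.25), Ccnf (1.67 ± 0.18), Cdc20, an activator of the anaphase-promoting complex (1.47 ± 0.26), and the formin gene Diap3 (1.45 ± 0.27). Each of these 5 fell under vehicle. The effect differed for 991 of 13973 genes (z test with Benjamini-Hochberg adjustment), with 487 values higher with Adriamycin and 504 lower. Of them 427 kept their sign and were smaller with Adriamycin, 100 kept their sign and were larger, and 464 changed sign. These signs were read from the fold changes alone, whether or not a gene passed the threshold. Only 79 genes passed it in both MEF tables with opposite signs, so most of the 464 are not shown to be reversals.

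At the level of lists, the difference between drug conditions in MEFs was towards lower values with Adriamycin for interferon-stimulated genes (adjusted p 9.72e-40), p53 targets (6.15e-19), the lysosome (1.79e-06), podocyte genes (0.00820) and leukocyte genes (0.0424). It was towards higher values for mitosis (1.05e-25), cytosolic ribosomal proteins (7.65e-17), DNA replication (6.79e-12), the mitochondrial ribosome (5.86e-08), homologous recombination (2.66e-07), the stress response (4.74e-06) and cholesterol synthesis (0.0379). With a correlation of 0.05, the calls of podocyte genes (adjusted p 0.135), leukocyte genes (0.147) and cholesterol synthesis (0.151) ended. The median mean count of the mitotic genes was 995 in the vehicle table and 86.8 in the Adriamycin table, and fold changes may be shrunk more at lower counts. Both tables moved alike in the main: 2923 genes passed the threshold in each, and 97.3% of them had the same direction (1464 higher and 1380 lower, where 447 and 488 would be shared by independent lists). The Spearman correlation across genes, which are not independent replicates, was 0.676. The least-squares slope of the Adriamycin values on those of vehicle was 0.513. Error in the vehicle values pulls such a slope towards 0, so division by it can scale the Adriamycin values up too far. With the Adriamycin values divided by that slope, the differences of Ifi44 (adjusted p 0.167), Isg15 (0.412), Usp18 (0.571) and Diap3 (0.0581) ended, and the direction of the lysosome turned (adjusted p 0.0249). The calls of homologous recombination (0.250), DNA replication (0.0557), podocyte genes (0.233), leukocyte genes (0.487) and cholesterol synthesis (0.100) ended as well. That scaling added calls for the antioxidant response (adjusted p 2.17e-06), the primary cilium (0.000390), glycolysis and hypoxia (0.0239) and housekeeping reference genes (0.0249), while those of mitosis and of interferon-stimulated genes held (0.000376 each).

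**Figure D2:**
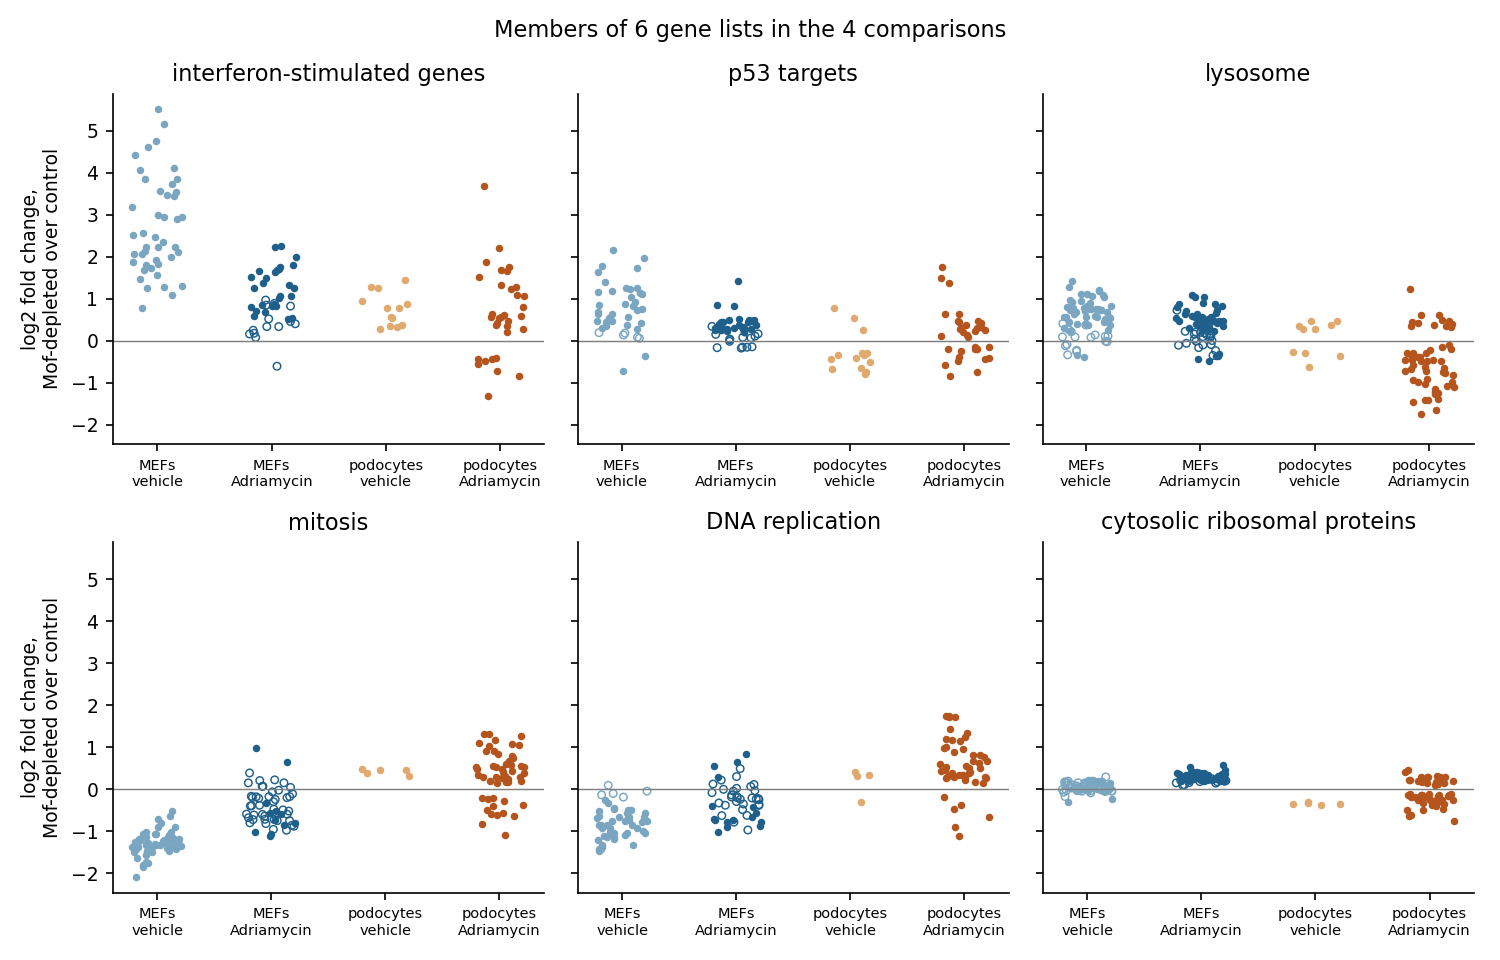
Log2 fold change (Mof-depleted over control) of each member of 6 gene lists in the 4 comparisons, filled where the adjusted p lies below 0.05; podocyte tables list no other genes. Interferon-stimulated genes with vehicle in MEFs have a median of 2.41, and the 60 mitotic genes there a median of -1.30.

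Knockdown and scrambled-control podocytes were compared under vehicle to ask which genes depend on MOF in a kidney cell. Genes of the podocyte list were mostly higher (16 of the 18 past the threshold; median 0.58), all 13 interferon-stimulated genes past it were higher (median 0.78), and p53 targets were mostly lower (11 of 14; median -0.38). In the authors' deposited table, 1990 genes changed, 1207 higher and 783 lower, of which 261 rose and 47 fell at least 2-fold; 13876 genes had been tested.

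Among named genes with a mean count of at least 100, those that rose in podocytes under vehicle included the kinesin gene Kif12 (2.83 ± 0.52), the cytokine receptor Il17rb (2.82 ± 0.39), the water channel Aqp1 (2.69 ± 0.23), C4bp, a complement regulator (2.40 ± 0.31), and the methyltransferase Inmt (2.34 ± 0.34) in the authors' deposited table. Others were choline dehydrogenase (Chdh, 2.33 ± 0.38), Txnip, an inhibitor of thioredoxin (2.08 ± 0.45), Nrxn2 (1.98 ± 0.27), aminopeptidase A (Enpep, 1.96 ± 0.25) and the septin gene Sept4 (1.94 ± 0.22) in the authors' deposited table. Cyclin D (Ccnd1, -1.60 ± 0.44), the AP-1 subunit Fosl1 (-1.58 ± 0.18), paraoxonase Pon2 (-1.43 ± 0.13), Serpinb9b (-1.40 ± 0.24), mesothelin (Msln, -1.31 ± 0.22), the peroxiredoxin gene Prdx6 (-1.20 ± 0.09), Erlin2 (-1.17 ± 0.08), sphingomyelin synthase (Sgms2, -1.16 ± 0.14) and Svop (-1.15 ± 0.15) fell in the authors' deposited table. Dystroglycan (Dag1, 0.75 ± 0.11) and nephronectin (Npnt, 0.88 ± 0.13) rose among podocyte genes in the authors' deposited table, and Itga3 (-0.37 ± 0.08) and Col4a4 (-0.75 ± 0.22) fell. Ifit3 (1.26 ± 0.18) and Ifit2 (0.55 ± 0.09) rose in the authors' deposited table. Of the p53 targets, Zmat3 (-0.73 ± 0.13) and Perp (-0.67 ± 0.11) fell, and Sesn1 (0.78 ± 0.13) and the BH3-only gene Bbc3 (0.55 ± 0.12) rose in the authors' deposited table.

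Because the podocyte tables list only genes past the threshold, a list was compared there with the other listed genes. Under vehicle the list test called p53 targets alone (adjusted p 0.0498). That call ended under each of 5 other settings (adjusted p 0.0606 to 0.210). An exact Fisher test of directions, chosen after the values were seen, called p53 targets and interferon-stimulated genes (adjusted p 0.0352 each), against 60.9% and 60.4% of the other genes higher, and not podocyte genes (0.0593). Of the lists with fewer members, 7 of 8 apoptosis genes were higher, among them Casp12 (1.38 ± 0.19) and Bcl2 (0.59 ± 0.10) in the authors' deposited table, and all 5 listed cytosolic ribosomal proteins were lower, with neither list past the test (adjusted p 0.127 and 0.112).

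With Adriamycin, 9578 of 17184 tested genes changed between knockdown and control podocytes in the authors' deposited table, 4776 higher and 4802 lower. Of these, 1179 rose and 1386 fell at least 2-fold. Among the changed genes, 72.7% of those with transcripts below 42% GC were higher, against 31.7% of those of at least 54%. Whether this trend is biological or technical was not tested. Genes of DNA replication rose (42 of the 48 past the threshold; median 0.51), and so did genes of homologous recombination and Fanconi anaemia repair (32 of 38; median 0.58) and of the actin cytoskeleton and focal adhesions (31 of 44; median 0.38). Lysosomal genes fell (42 of 54; median -0.48), as did autophagy genes (23 of 30; median -0.39).

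Among named genes with a mean count of at least 100, Ms4a2, a chain of the IgE receptor, had the largest increase with Adriamycin. It was at 4.81 ± 0.25 with a mean normalized count of 752 in the authors' deposited table. Abi3bp (4.17 ± 0.34), Ifit3 (3.67 ± 0.31) and Txnip (7.97-fold, adjusted p listed as 0) rose as well in the authors' deposited table. Others that rose were the semaphorin Sema5a (2.94 ± 0.10), cadherin Cdh11 (2.87 ± 0.15), the myosin light chain Myl9 (2.66 ± 0.22), the growth factor receptor Csf1r (2.65 ± 0.18) and Ctgf (2.54 ± 0.21) in the authors' deposited table. Among genes with a mean count of at least 100, those that fell included Cited1 (-4.15 ± 0.28), Adap1 (-3.47 ± 0.20), the pentraxin Nptx1 (-3.29 ± 0.11), Foxo6 (-3.15 ± 0.12), Ccno (-3.08 ± 0.15), the collagen gene Col11a2 (-3.02 ± 0.16), Ndrg4 (-3.01 ± 0.16), Slc23a3 (-2.96 ± 0.17), the plexin gene Plxnc1 (-2.90 ± 0.15) and the lysosomal transporter gene Abcb9 (-2.81 ± 0.08) in the authors' deposited table. Ribonucleotide reductase Rrm1 (1.44 ± 0.05), Uhrf1 (1.24 ± 0.05), topoisomerase Top2a (1.17 ± 0.05), the damage kinase Atm (1.24 ± 0.07) and the tropomyosin gene Tpm1 (1.06 ± 0.04) rose in the authors' deposited table. Chaf1b (-1.12 ± 0.06), Cenpe (-0.83 ± 0.04) and Rad50 (-0.43 ± 0.05) went against their lists in the authors' deposited table. Cathepsin A (Ctsa, -1.42 ± 0.05), Npc2 (-1.22 ± 0.05), Wipi1 (-1.51 ± 0.06) and the late endosomal GTPase gene Rab7 (-0.84 ± 0.04) fell in the authors' deposited table. Among podocyte genes (20 higher and 14 lower), the nephrin relative Kirrel (1.53 ± 0.06) and ezrin (Ezr, 1.28 ± 0.05) rose and Vegfa (-1.27 ± 0.05) and Npnt (-0.84 ± 0.06) fell in the authors' deposited table.

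The list test with Adriamycin, again among listed genes, called 7 lists in podocytes: DNA replication (adjusted p 5.15e-08), the lysosome (2.30e-06), homologous recombination and actin cytoskeleton (0.000121 each), mitosis (38 higher and 13 lower; 0.00284), autophagy (0.0192) and the nuclear-encoded respiratory chain (15 higher and 42 lower; 0.0412). With a correlation of 0.05 the calls of mitosis (adjusted p 0.129), autophagy (0.176) and the respiratory chain (0.356) ended, and with the fold change as the statistic those 3 (0.0948, 0.280 and 0.399) and that of actin cytoskeleton (0.0973) ended.

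Among the 1518 genes listed in both podocyte tables, the effect of the knockdown differed between drug conditions for 962, with 478 values higher with Adriamycin and 484 lower. Genes that fell under vehicle and rose with Adriamycin included the matricellular gene Ctgf (difference 3.40 ± 0.23), the muscle ankyrin repeat gene Ankrd1 (2.85 ± 0.25), Ikzf2 (2.59 ± 0.20) and smooth muscle actin (Acta2, 2.56 ± 0.13), from the authors' deposited table of each drug condition. Ms4a2 rose in both and differed by 3.20 ± 0.50. Rhbdl3 (-3.89 ± 0.39), Angpt4 (-3.67 ± 0.23), Sned1 (-3.60 ± 0.40), Gpr146 (-3.25 ± 0.21) and Pkdcc (-3.16 ± 0.20) rose under vehicle and fell with Adriamycin in the authors' deposited table of each. The sign changed for 521 of the 962, 390 kept their sign and were larger with Adriamycin, and 51 were smaller. Over all 1518 genes, 65.7% had the same direction in both tables (Fisher's exact test, p 4.79e-33; Spearman correlation across genes 0.315). These genes were preselected by passing the threshold in both tables, so the share that differed cannot be set against that of MEFs.

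The effects in MEFs and podocytes were then set side by side. Under vehicle, 890 genes passed the threshold in both cell types and 61.3% of them had the same direction (Fisher's exact test, p 1.83e-10). The Spearman correlation across these genes was weak, at 0.159. With a threshold of 0.01 the share was 58.4% of 401 genes (Fisher's exact test, p 0.0151). Genes are not independent replicates, so these p-values may be too small. Kat8 fell in both, and Bai1 (2.44 ± 0.52 in MEFs and 2.18 ± 0.43 in podocytes), Trim17 (2.47 ± 0.68 and 2.17 ± 0.48), the interferon-induced kinase gene Cmpk2 (2.85 ± 0.39 and 1.71 ± 0.46), the histone gene Hist3h2a (1.66 ± 0.21 and 1.86 ± 0.44), Gpr123 (1.56 ± 0.43 and 2.93 ± 0.52), Ano5 (1.42 ± 0.50 and 1.74 ± 0.42) and the peptidase gene Dpp4 (2.64-fold and 2.69-fold) rose in both in the authors' deposited table. Abi3bp (-2.08 ± 0.26 and 1.89 ± 0.33) and Btn1a1 (3.31 ± 0.56 and -1.48 ± 0.45) went opposite ways in the authors' deposited table. Most of these genes had mean normalized counts below 100, with 127 and 5801 for Abi3bp and 151 and 21.6 for Hist3h2a.

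With Adriamycin, 3191 genes passed the threshold in both cell types, and 25.5% had the same direction: 1257 were higher in MEFs and lower in podocytes and 1119 the reverse (Fisher's exact test, odds ratio 0.118, p 3.65e-174; Spearman correlation across genes -0.540). Abi3bp was at -2.56 ± 0.29 in MEFs and 4.17 ± 0.34 in podocytes, the septin gene Sept1 at 1.62 ± 0.23 and -1.62 ± 0.14, and the transcription factor Pou3f1 at 1.63 ± 0.35 and -3.16 ± 0.28 in the authors' deposited table. Fgfbp1 rose in both (1.59 ± 0.42 and 1.71 ± 0.58) in the authors' deposited table, at low mean normalized counts of 18.4 in MEFs and 7.18 in podocytes. Those of Pou3f1 were 36.7 and 71.8. Lysosomal genes were 40 higher and 5 lower in MEFs and 12 and 42 in podocytes (Fisher's exact test, adjusted p 1.68e-10), and cytosolic ribosomal proteins were 67 and 0 against 22 and 33 (4.15e-14). DNA replication was 4 higher and 12 lower in MEFs and 42 and 6 in podocytes (3.02e-05), and the primary cilium 1 and 33 against 25 and 19 (1.11e-06). The same gene can count in both cell types and members can move together, so these p-values of Fisher's exact test may be too small. These lists were not compared with the other genes. The fold changes also moved with the GC content of the transcripts, in opposite directions (Spearman correlation across genes 0.273 in MEFs and -0.317 in podocytes). With GC content and length taken out, an alternative chosen after the values were seen, the shared direction was 29.6%.

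**Figure D3:**
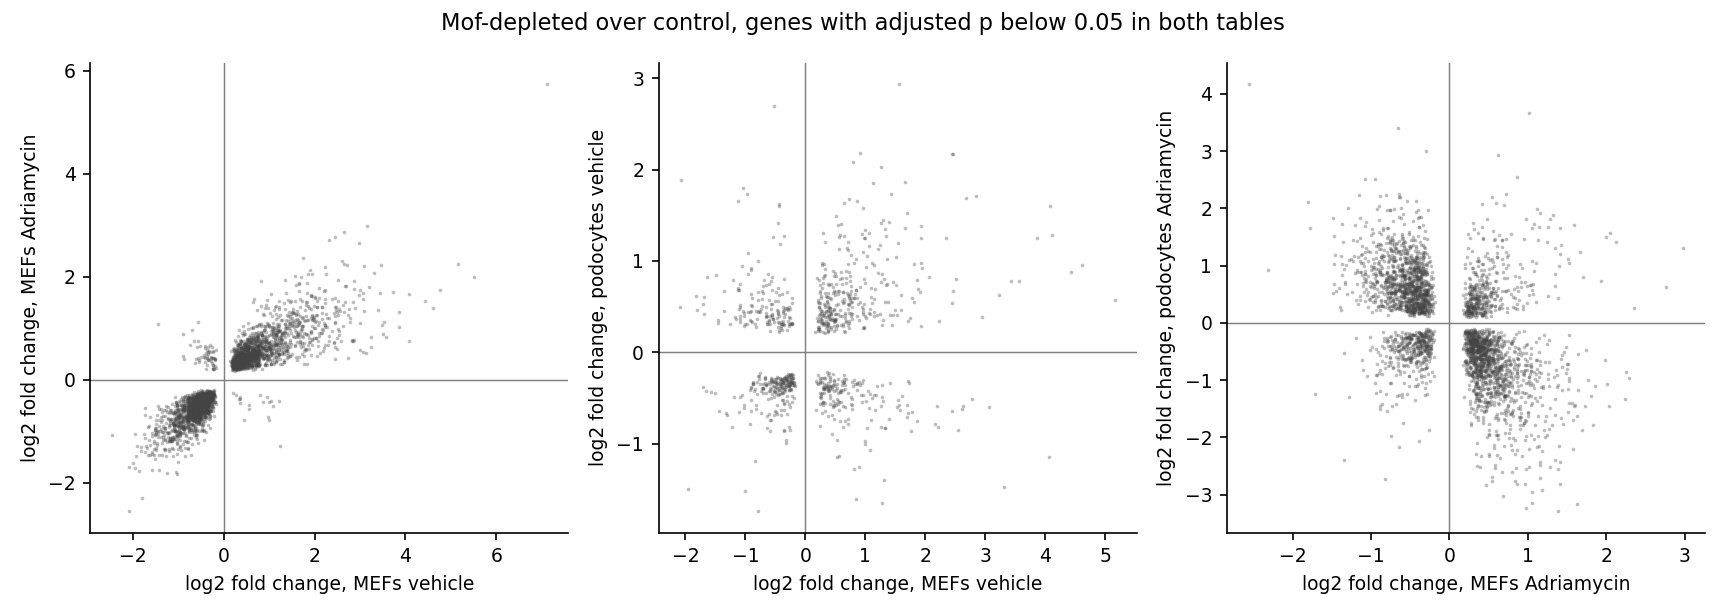
Log2 fold changes (Mof-depleted over control) of genes with an adjusted p below 0.05 in both of the tables set against each other, 1 point per gene. The direction was shared by 97.3% of 2923 genes between MEF tables (left), 61.3% of 890 between cell types with vehicle (middle) and 25.5% of 3191 with Adriamycin (right).

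MOF acts on the X chromosome of flies, and X-linked genes were therefore compared with autosomal genes (mean count of at least 100, permutation of 100000 draws, two-sided, across genes). In MEFs the median of X-linked less autosomal genes was -0.01 with vehicle (permutation p 0.666) and -0.10 with Adriamycin (permutation p 3e-05, 352 X-linked genes), the latter -0.04 with GC content and length taken out (p 0.0488). Among the listed podocyte genes it was 0.06 with vehicle (permutation p 0.403) and 0.33 with Adriamycin (permutation p 0.166). With Adriamycin it passed the threshold in podocytes at a mean count of at least 10 (0.65, permutation p 1e-05, the smallest these draws can give) or 1000 (0.47, p 0.00375), and with GC content and length taken out (0.24, p 0.00132). Podocyte genes that did not change are not listed, so values near 0 are missing and a median can jump across that gap. The autosomal median was 0.127 at a count of at least 100, -0.129 at 10 and -0.207 at 1000. The size of the podocyte difference is therefore not stable. Of the tested genes within 1 Mb of Kat8, 25 of 64 changed in MEFs with vehicle (Fisher's exact test against other genes, odds ratio 1.06, p 0.798) and 16 of 61 with Adriamycin (odds ratio 0.731, p 0.339). One of them is Trim72, which rose by 1.69 ± 0.40 in MEFs with Adriamycin and fell in podocytes (-1.86 ± 0.45) in the authors' deposited table. Its mean normalized counts were low, at 21.9 in MEFs and 16.3 in podocytes.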

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

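The tests in this part that were chosen only after the results were seen are the comparison of directions between cell types, the list differences between drug conditions with their slope-scaled form, regression on GC content and length, the leukocyte test and the test of interferon-stimulated genes in podocytes. The gene lists, the threshold, the rule for named genes, the gene-level difference test and the choice to use the deposited statistics if no sample values were found were made before the data were examined.

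A difference in the effect of Mof loss between drug conditions drew attention to 991 of 13973 genes in MEFs and 962 of 1518 in podocytes (z test with Benjamini-Hochberg adjustment). The podocyte genes had been preselected by passing the threshold in both tables, so these shares cannot be set against each other. In MEFs the difference (Adriamycin less vehicle) was 2.29 for Cep128, 1.78 for Fam83d, 1.67 for Ccnf, 1.47 for Cdc20 and 1.45 for Diap3, and -3.51 for Ifi44, -3.33 for Svop, -3.22 for Irf7, -3.01 for Isg15 and -2.92 for Usp18. In podocytes it was 3.40 for Ctgf, 3.20 for Ms4a2, 2.85 for Ankrd1, 2.59 for Ikzf2 and 2.56 for Acta2, and -3.89 for Rhbdl3, -3.67 for Angpt4, -3.60 for Sned1, -3.25 for Gpr146 and -3.16 for Pkdcc.

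Of the gene lists in MEFs, the difference passed the test (cameraPR of limma) for p53 targets (adjusted p 6.15e-19), homologous recombination and Fanconi anaemia repair (2.66e-07), the lysosome (1.79e-06), the mitochondrial ribosome (5.86e-08), cytosolic ribosomal proteins (7.65e-17), mitosis (1.05e-25), DNA replication (6.79e-12), podocyte genes (0.00820), macrophage and leukocyte genes (0.0424), interferon-stimulated genes (9.72e-40), the integrated stress and unfolded protein response (4.74e-06) and cholesterol synthesis (0.0379). With a correlation of 0.05 between genes, the calls of podocyte genes (0.135), leukocyte genes (0.147) and cholesterol synthesis (0.151) ended. Slope scaling turned the lysosome (0.0249) and ended the calls of homologous recombination (0.250), DNA replication (0.0557), podocyte genes (0.233), leukocyte genes (0.487) and cholesterol synthesis (0.100), and with the fold change as the statistic the calls of the lysosome (0.138) and of podocyte genes (0.0575) ended. At a mean count of at least 100, cholesterol synthesis ended (0.0752). Error in the vehicle values pulls the slope towards 0, so slope scaling can overshoot.

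The directions of list members differed between MEFs and podocytes by Fisher's exact test. That test takes the counted genes as independent. Members of a list can move together, and the same gene can be counted in both cell types, so its p-values may be too small. Under vehicle this held for p53 targets (34 higher and 2 lower in MEFs, 3 and 11 in podocytes; adjusted p 5.57e-06), the lysosome (49 and 2, 6 and 4; 0.0172), cytosolic ribosomal proteins (9 and 2, 0 and 5; 0.0172), mitosis (0 and 60, 5 and 0; 2.06e-06), the antioxidant response (18 and 0, 4 and 6; 0.00316) and the primary cilium (2 and 28, 3 and 2; 0.0393). The MEF counts of cytosolic ribosomal proteins under vehicle were 1 and 1 when adjusted over the list alone, so that difference rests on few calls. With Adriamycin it held for p53 targets (26 and 0, 20 and 13; 0.000701), homologous recombination and Fanconi anaemia repair (2 and 10, 32 and 6; 0.000140), the lysosome (40 and 5, 12 and 42; 1.68e-10), autophagy (9 and 6, 7 and 23; 0.0415), endosomal trafficking (23 and 6, 14 and 38; 3.02e-05), cytosolic ribosomal proteins (67 and 0, 22 and 33; 4.15e-14) and mitosis (2 and 10, 38 and 13; 0.000977). It held as well for DNA replication (4 and 12, 42 and 6; 3.02e-05), fibroblast and mesenchymal genes (2 and 11, 11 and 8; 0.0444), interferon-stimulated genes (28 and 0, 25 and 8; 0.0127), the antioxidant response (19 and 0, 16 and 12; 0.00152), glycolysis and hypoxia (12 and 2, 6 and 10; 0.0212), the primary cilium (1 and 33, 25 and 19; 1.11e-06) and actin cytoskeleton and focal adhesion (8 and 12, 31 and 13; 0.0444). Of all genes past the threshold in both cell types, 61.3% of 890 had the same direction with vehicle and 25.5% of 3191 with Adriamycin. The lists were not compared with the other genes, so these differences cannot be called particular to them. Cell type and knockout against knockdown differed together, and with Adriamycin the drug dose as well, so none of these differences can be assigned to the cell type alone.

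Interferon-stimulated genes were higher in knockout MEFs with vehicle, with a median log2 fold change of 2.41. A bias by GC content and length would be removed by regression, which left 100.3% of the median (97.8% to 105%). A response to Mof loss in more than one cell type may be a part of it, since all 13 interferon-stimulated genes listed in podocytes with vehicle were higher (Fisher's exact test, p 0.00255), although the competitive list test there missed the threshold (adjusted p 0.112). Leukocytes in the knockout cultures stay open: the median of the 19 tested leukocyte genes lay below that of the list (-1.59, bootstrap interval -2.36 to -1.25), but such genes were read in the controls too, a baseline that can hide a larger share. The levels of the leukocyte list ran from a mean count of 1924 for Lyz2 (log2 fold change 1.29) to 9.46 for Aif1 (1.08 ± 0.60). Between them lay Csf1r at 351 (-0.12) and Ptprc at 58.1 (0.36). These genes were chosen after their values were seen. With Adriamycin 0 of 18 leukocyte genes passed the threshold (DESeq2 as run by the authors) where 28 of 42 interferon-stimulated genes rose. An infection, an effect of the way of knockout, or a difference of embryo, culture or day between genotypes was not tested and stays open.

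Esr1 was higher in knockout MEFs, by 7.11 with vehicle. Activation of the region around it would raise its neighbours, of which 3 of the 13 tested within 1 Mb rose (23.1%). A transgene carrying Esr1 sequence in the knockout cells may be the source, as the median of the neighbours was -0.12 (they ranged from -1.09 to 1.07). This remains a hypothesis: the labels name no such construct, no reads were at hand, and the absence of Esr1 from podocyte tables that list changed genes alone excludes nothing. Regulation of Esr1 itself by MOF stays open too.

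More genes passed the threshold in podocytes with Adriamycin (9578) than with vehicle (1990). Smaller standard errors, from less spread between libraries or greater depth, were not the whole of this: widened by the ratio between the tables (1.58), they left a count of 7240, still above that with vehicle. Larger effects may contribute: the absolute log2 fold change was 1.31 times as large with Adriamycin in the median of 1518 genes found in both tables (1.24 to 1.38), genes that had passed the threshold in each. A difference of culture, passage or library preparation between the drug conditions was not tested and stays open. The fold changes of changed genes also moved with GC content (Spearman correlation across genes -0.317 with Adriamycin and 0.0943 with vehicle). How many of the calls go with that trend was not tested.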

How the results depend on the processing

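Of these alternatives, regression on GC content and length, Fisher's test of directions in podocytes and the slope scaling of lists were chosen after the data were seen. Of the alternative values of results that answer a comparison, 67 kept their call or, for counts, stayed within 1.5 times the count reported; 22 counts moved further, 3 values newly passed the threshold and 2 changed sign. Changed genes at an adjusted p of 0.01 were 3077 in MEFs with Adriamycin and 1182 in podocytes with vehicle. At least 2-fold were 1322 and 554 in MEFs with vehicle and Adriamycin and 308 and 2565 in podocytes, fewer by construction. After recentring on the median, with an absolute log2 fold change above 0.58, they were 2777, 1895, 1060 and 5436. Of these, 305 were higher and 755 lower in podocytes with vehicle, against 605 and 205 without recentring, and 2010 and 3426 with Adriamycin, against 2589 and 2761; in MEFs they were 1605 and 1172 with vehicle, against 1492 and 1339, and 974 and 921 with Adriamycin, against 934 and 979. In podocytes that median (0.33 and 0.14) is over changed genes, so it is not the centre of all genes; it turned the sign with vehicle of Msl2 (-0.0408), Mdc1 (-0.0221), Calcoco1 (-0.0346), Rab5b (-0.103) and Mrpl49 (-0.0116) and with Adriamycin of mt-Cytb (-0.0186), by construction. With a correlation of 0.05, 10 and 6 lists were called in MEFs with vehicle and Adriamycin and 0 and 4 in podocytes; with the fold change as the statistic, 4 in podocytes with Adriamycin. In podocytes with vehicle 0 were called with ranks, the fold change, a mean count of at least 100 or regression on GC content and length, and 2 by Fisher's test. Alternatives also added calls: with the fold change as the statistic, epithelial (adjusted p 0.000245), skeletal muscle (0.00193) and inflammatory genes (0.00205) in MEFs with Adriamycin and interferon-stimulated genes (0.00351) in podocytes with Adriamycin. With GC content and length taken out, mitochondrially encoded genes (0.0400), the mitochondrial ribosome (0.0321), MOF and its paralogs (0.0457) and housekeeping genes (0.0345) were called in MEFs with Adriamycin, and mitochondrially encoded (0.00796) and epithelial genes (0.0194) in podocytes with Adriamycin. Fisher's test of directions added endosomal trafficking (14 higher and 38 lower, 0.00562) and interferon-stimulated genes (25 and 8, 0.0117) in podocytes with Adriamycin. Ranks added the mitochondrial ribosome (0.0365) in MEFs with Adriamycin and, for the difference, the respiratory chain (0.0266) and mitochondrially encoded genes (0.0267, and 0.0377 at a mean count of at least 100). The difference between drug conditions in MEFs held for 486 genes at 0.01 and 1500 at 0.1. That of the lysosome turned with slope scaling (cameraPR, adjusted p 0.0249), a scaling that can overshoot. Its adjusted p ran from 6.80e-07 to 0.138 over the alternatives, and the cause was not tested. The X-linked less autosomal median turned in MEFs with vehicle at a mean count of at least 1000 (0.0478) and with GC content and length taken out (0.0194), and the cause was not tested. In podocytes with Adriamycin it was 0.65 and 0.47 at at least 10 and 1000 and 0.24 with GC content and length taken out. There the autosomal median, over changed genes alone, itself moved from 0.127 at a count of at least 100 to -0.129 at 10 and -0.207 at 1000. Of named genes, 1148 alternative values kept their call; Esam, mt-Nd5, Dcn, Elavl4 and Ncam1 lost it in MEFs when each gene with a p was adjusted together. For the genes changed in podocytes, a threshold of 0.1 and recomputed filters could not be run, since the tables end at 0.05; the overlaps with podocytes could not be run at 0.1 either. The podocyte difference between drug conditions at 0.1 gave 1026 genes among those listed in both. Other size factors, another test, pseudocounts, a replicate block and left-out replicates could not be run without values per sample. No paired analysis was possible because the tables used here hold no value per sample. Depth per library is not known; in the simulation 20.1% of differences of 0.5 were recovered, so smaller differences between drug conditions would mostly be missed.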

Other observations

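No test in this part was planned; the values below are described only. Mean normalized counts of the MEF tables, which the authors normalized separately, were set side by side without a test. They were lower with Adriamycin for mitosis (median log2 ratio -3.97, with 59 of 60 genes below -1), DNA replication (-2.53, 45 of 50) and homologous recombination (-1.39, 27 of 46), and higher for p53 targets (0.79, with 15 of 41 above 1). Mitotic genes were thus read at lower counts in the Adriamycin comparison, where 12 of 57 passed the threshold against 60 of 60 with vehicle.

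The log2 fold changes moved with the GC content of transcripts, with a Spearman correlation across genes of 0.119 in MEFs with vehicle, 0.273 in MEFs with Adriamycin, 0.0943 in podocytes with vehicle and -0.317 in podocytes with Adriamycin. Genes below 42% GC had a median of 0.44 in podocytes with Adriamycin, and those of at least 54% a median of -0.48. In MEFs with Adriamycin these medians were -0.21 and 0.12.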
